A study of Anopheles gambiae with 16 samples.

How the data were processed

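Gene expression was measured in adult females of the malaria mosquito Anopheles gambiae, G3 strain, taken 1 to 2 days after eclosion and described as naive in the series design. The 16 arrays fall into 4 groups of 4, each array being a separate biological replicate per the labels: heads, carcasses and circulating hemocytes labelled after 2 rounds of amplification from 80 ng of total RNA, and carcasses labelled after 1 round from 1000 ng. Hemocytes are the blood cells of insects, and carcass here means the body left after hemolymph was drawn and the head removed. Per the labels, a head pool came from 40 females and a carcass pool from 20, while hemolymph was drawn by clipping the proboscis and pressing the thorax. The hemocyte labels conflict on the pool, with 1000 females in the source name and 500 in the collection note, which also calls the females infected. Head replicate 4 has a source name that speaks of carcasses from 20 females, whereas its title, description and tissue entry say head, so it was kept as a head array, and the counts of calls, of probe sets higher in a tissue than in both others and of probe sets above background were repeated without it. Hemocyte RNA went straight into a column kit buffer, while heads and carcasses were first extracted with Trizol. Tissue can therefore not be told apart from collection or, for hemocytes, from extraction method.

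The deposited values are intensity values on a linear scale, 1 per probe set and array, for 22761 probe sets. The authors used GCOS 1.4, the scanner and expression software of the array maker, per the submitters' processing notes. The summary method, background step and scaling are not given in the sources used here, and no common target could be read from the values, since the trimmed mean intensity (2% off each end) ranged from 82.8 to 159 between arrays. All values were above 0. No further normalization was applied for the reported values.

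Probe sets are named only by their array IDs, and the files do not pair these with genes. None of the IDs matched the gene table given for the species (15165 genes, assembly idAnoGambNW_F1_1; 0 matches), so no gene is named from an ID. The 25 gene lists fixed in advance (immune, head, carcass and housekeeping lists) therefore matched 0 probe sets and their shifts could not be tested, and the rule for naming genes named none. In its place, and chosen after the IDs were seen, the 2 probe sets with the largest rise and the 2 with the largest fall are named per comparison, among those past the threshold whose arrays do not overlap between the groups. IDs that begin with Ag. (16884) were read as mosquito probe sets and those with Pf. as probe sets of the malaria parasite carried on the same array, a reading of the prefixes that no source used here records. An Ag. ID also holds a chromosome arm (2L, 2R, 3L, 3R, X, or UNKN where none is given) and either the mark CDS, the mark UTR or neither, and these were used as probe set groups, a use decided after the IDs were seen. Coordinates were not used here.

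Values were taken as log2 of intensity plus a pseudocount of 16, so fold changes understate the change of dim probe sets. One linear model over the 4 groups (12 residual degrees of freedom) was fitted to the Ag. probe sets with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), followed by Benjamini-Hochberg adjustment per comparison. A probe set was called at an adjusted p under 0.05 and a change of at least 2-fold. Background was set per array at the 95th percentile of the Pf. probe sets, between 8.83 and 15.28 intensity units. Where a probe set lay below it on all 4 arrays of a group, the fold is given as a bound, the geometric mean of the bright group over that of the higher of background and measured value per array. Bright probe sets, meaning those above background on at least 4 arrays (13061), were the basis of Fisher's exact tests on arms (48 tests) and classes (24 tests) and of limma's camera, run with its preset correlation of 0.01 and again with an estimated one. The Fisher tests count probe sets of the same arrays as independent, so their p does not measure the spread between arrays. Control probe sets of actin and Gapdh were compared on log2 intensity with an exact two-sided permutation test, for which 4 arrays against 4 can give no p below 0.029, with adjustment over 40 tests. Between the 2 carcass groups these values were also permuted within the 4 pairs of replicate numbers, where no p below 0.125 is possible.

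On simulated data built from the measured means and spreads, with 100 probe sets changed 3-fold and 100 changed 8-fold among 16884, the procedure recovered 92% of 3-fold and 100% of 8-fold changes for hemocyte over carcass, 94% and 100% for hemocyte over head, 92% and 98% for head over carcass, and 96% and 100% for 2 rounds over 1 round, with 4, 2, 3 and 5 false calls. These changes were added to the log2 values with the pseudocount in place. In intensity a dim probe set needs a larger fold for the same change, so the rates overstate recovery there. The number of arrays limits the precision of all values. At most 1 value was identical between any 2 arrays, so no array was a copy of another. Arrays with the same replicate number deviated together from their group means at all 4 numbers only between the 2 carcass groups. Their correlations over bright probe sets were 0.424, 0.242, 0.54 and 0.295 for numbers 1 to 4, each higher than with any other number. These numbers thus pair the carcass arrays, though the labels do not say whether both labellings came from the same pool. Heads matched carcasses of their own number best at numbers 1 (0.174 with two-round and 0.195 with one-round arrays) and 3 (0.083 and 0.031), and not at 2 and 4. No other pair of groups matched at all 4 numbers.

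Planned before the data were examined were quantile normalization, median centring, a filter on dim probe sets, pseudocounts of 1 and 64, fits of only the groups compared, the replicate number as a block, an intensity trend with robust settings, removal of probe sets ending in _x_at or _s_at, and leaving out each array in turn. A mean over the probe sets of a gene was planned and not run, since no gene is known for a probe set. Scaling on the hybridisation spike-ins, one-round carcasses as reference, the block within the carcass arrays, a 99th percentile background, and the alternatives for class shifts, detection and control ratios were chosen after seeing the data. The class and arm shares, themselves chosen after the IDs were seen, were run under the settings planned for the calls and under spike-in scaling. Chosen after seeing the data were also the splits and simulations for lower calls shared between contrasts and for calls shared between the 2 carcass references, the bounds with 1 array left out, and the permutation within pairs. In such a split replicates 1 and 2 of the tissue entered one contrast and 3 and 4 the other. Probe sets named by other prefixes were not used in the comparisons.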

Results

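Transcript levels were measured on 16 arrays, 4 each for heads, circulating hemocytes and carcasses of adult Anopheles gambiae females after 2 rounds of amplification and 4 for carcasses after 1 round. The series sets these tissues side by side to profile where transcripts are expressed, and the carcass samples labelled both ways allow the 2 labellings to be compared. The median intensity of the Ag. probe sets lay between 19.07 and 27 on all arrays, against 1.367 to 2.691 for the Pf. probe sets, and 10050 to 11888 of the 16884 Ag. probe sets lay above background on an array. Probe sets above background on all 4 arrays of a group numbered 8516 in heads, 8230 in two-round carcasses, 9036 in one-round carcasses and 8073 in hemocytes. A common set of 6369 (37.7%) was above background on all 12 two-round arrays, and 1563 (9.26%) were above it on none of the 16 arrays.

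The arrays parted mainly by tissue group, which cannot be told apart from collection or, for hemocytes, from extraction method. Hemocytes stood apart on the first principal component, which held 47.8% of the variance, with positions from -107.1 to -97.8 against -17.8 to 68 for all other arrays. Heads stood apart on the second component (24.4%), at 66.3 to 81.4 against -45.5 to -3.7. The third component (8.43%) held the 2 carcass labellings apart, at -44.7 to -37 after 2 rounds and 20.6 to 33.5 after 1 round. They were also apart on the first component, at 33.5 to 37.4 after 2 rounds and 59.7 to 68 after 1 round. On the second they lay at -16 to -3.7 and -45.5 to -29.1. Correlations between arrays of one group were 0.9298 to 0.9756, and those between groups were 0.7305 to 0.9329. Head replicate 4, the array with the conflicting source name, correlated at 0.9721 with the mean of the other heads and at 0.8869 with two-round carcasses. These correlations are across probe sets, which are not independent replicates.

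**Figure D1:**
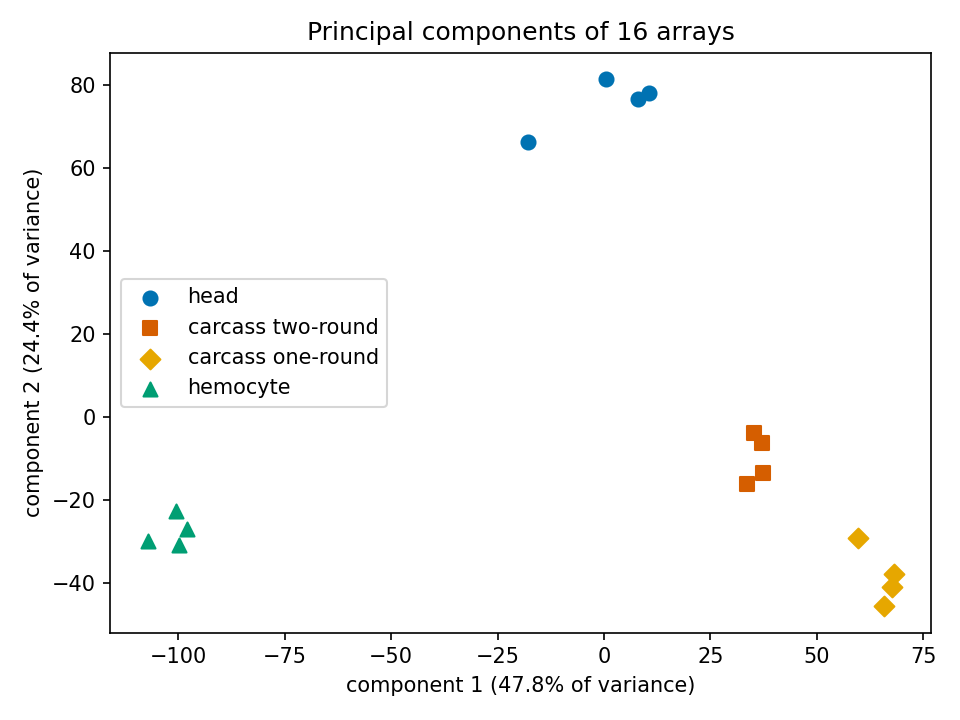
Each point is 1 of 16 arrays, placed by its scores on principal components 1 (horizontal, 47.8% of variance) and 2 (vertical, 24.4%) of log2 intensities of Ag. probe sets; colour and shape give the group. The 4 hemocyte arrays lie between -107.1 and -97.8 on component 1 and the 4 head arrays between 66.3 and 81.4 on component 2.

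The comparison of hemocytes with carcasses asked which transcripts blood cells hold at other levels than the rest of the body. Probe set Ag.2R.1112.0_CDS_at, on arm 2R by its ID, measured 3610 ± 1270 in hemocytes (SD, n = 4) and 56.85 ± 20.5 in two-round carcasses, a log2 difference of 5.61 ± 0.34 (SE, limma adjusted p = 3e-09). Ag.UNKN.1005.1_at, with no arm in its ID, measured 6452 ± 2140 against 132.8 ± 80.7, a difference of 5.54 ± 0.37 (limma adjusted p = 7.7e-09). In the other direction Ag.3R.157.14_a_at was at least 500-fold lower in hemocytes, where it was below background on all 4 arrays, than in carcasses (6822 ± 2700; limma adjusted p = 2.5e-11). Ag.2L.245.0_CDS_at was at least 442-fold lower, also below background on all 4 hemocyte arrays, against 5671 ± 352 in carcasses (limma adjusted p = 4.9e-06). Actin, a main part of the cytoskeleton, gave higher values in hemocytes at all 3 of its control probe sets, 1.44-fold at the 3' end, 2.17-fold in the middle and 2.85-fold at the 5' end (exact two-sided permutation test, adjusted p = 0.0497 for each). The unadjusted p was 0.029, the smallest that 4 arrays against 4 can give, here and wherever an adjusted p of 0.0497 stands, and the 3 directions were the same under each of 3 other scalings. The adjusted p came out at 0.0497 only because many of the 40 tests had this smallest p. Among them were tests between the paired carcass labellings, which did not pass within pairs. Whether the tissue differences at 0.0497 pass rests on including those tests, and an adjustment without them was not run. The 3' over 5' ratio of actin was 1.98-fold lower in hemocytes, and its 3' over middle ratio 1.51-fold lower (adjusted permutation p = 0.0497 for both). Gapdh, a glycolytic enzyme, did not pass at any of its 3 control probe sets, with log2 differences of 0.2, -0.18 and -0.33 and adjusted permutation p of 0.471, 0.649 and 0.45.

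Of the 16884 probe sets, 1812 were called higher and 1380 lower in hemocytes than in two-round carcasses, and 5695 passed the adjusted p with no fold minimum. With quantile normalization lower calls outnumbered higher ones, at 1399 against 1325. The large changes ran mostly downwards, with 28 probe sets at least 16-fold higher and 260 at least 16-fold lower. Among bright probe sets, 18.7% of the 775 marked UTR were called lower against 10.1% of the others (odds ratio 2.06, Fisher's exact test, adjusted p = 7.2e-12), beside the lower actin ratios given above and Gapdh ratios that did not pass (0.54 for 3' over 5' and 0.38 for 3' over middle on the log2 scale, adjusted permutation p = 0.122 and 0.0879). Called lower were also 12.4% of those on arm 2L against 10.1% of the others (adjusted p = 0.0033), which was lost with a pseudocount of 64 (adjusted p = 0.17). UNKN probe sets were called less often in both directions, 7.14% against 14.5% higher (adjusted p = 3.4e-11) and 5.35% against 11% lower (adjusted p = 7.7e-09). Median shifts of arms and classes did not pass camera, with adjusted p of 0.93 for each of the 9 groups. The Fisher tests above count probe sets as independent, which they are not, so their p does not measure the spread between arrays. The odds ratio for lower calls of UTR probe sets was 1.68 with a pseudocount of 1 and 2.58 with 64. Its share was not matched on brightness. Of the called probe sets, 3091 had no overlap between the 4 arrays of each group, and 33.5% of all probe sets had none, where chance gives 2.86%. With one-round carcasses as the reference, 3169 were called higher, and 2644 calls were shared in direction with the 3192 made against two-round carcasses. Both lists use the same hemocyte arrays. Independent lists would share 464.3, and with 2 hemocyte arrays in each list 2504 were shared against 494.6, while the 2 carcass groups are themselves paired by number. Simulations with unchanged groups made at most 1 call and so had 0 to share, which says nothing of lists this long.

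The comparison of hemocytes with heads named Ag.2R.1112.0_CDS_at again as the largest rise, at 3610 ± 1270 against 47.79 ± 27.6 (SD, n = 4; log2 difference 5.86 ± 0.34 SE, limma adjusted p = 2.3e-09). Ag.2R.2035.0_CDS_at measured 1860 ± 1110 in hemocytes and 15.16 ± 13.5 in heads, where 2 of 4 arrays were above background (difference 5.79 ± 0.42, limma adjusted p = 2.2e-08). The largest falls were at a pair of probe sets on arm 3R. Ag.3R.3.3_UTR_a_at measured 15550 ± 1140 in heads and 399.1 ± 796 in hemocytes, a log2 difference of -8.18 ± 1.02 (limma adjusted p = 8.6e-06), and Ag.3R.3.1_CDS_a_at measured 10850 ± 1770 and 99.74 ± 194, a difference of -8.06 ± 0.71 (limma adjusted p = 1.8e-07). Both were above background on 1 of 4 hemocyte arrays, replicate 4, and against the other 3 arrays, all below background, they were at least 1200-fold and 831-fold lower. Actin was 2.07-fold higher in hemocytes at its middle and 2.08-fold at its 5' probe set (exact permutation test, adjusted p = 0.0497 for both), and Gapdh was 2.55-fold higher at its middle probe set (adjusted p = 0.0497), with the same directions under each of 3 other scalings. The 3' over middle intensity ratio was 2.24-fold lower in hemocytes for Gapdh and 1.59-fold lower for actin (adjusted permutation p = 0.0497 for both). The 3' probe sets of both genes did not pass, with log2 differences of 0.38 (adjusted permutation p = 0.0879) and 0.19 (0.49). Median centring moved the median difference of all probe sets from 0 to 0.15.

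Between hemocytes and heads 1872 probe sets were called higher and 1570 lower, out of 5888 that passed at any fold, with 51 and 177 of them changed at least 16-fold. Lower calls were more frequent among UTR probe sets, at 21% against 11.4% of the others (Fisher's exact test, adjusted p = 5.4e-13), and among unmarked ones, at 16.4% against 11.3% (adjusted p = 9.3e-09), than among CDS ones, at 10.6% (adjusted p = 2.4e-21 against all others). The control ratios that passed were lower in hemocytes as well, namely 3' over middle for both genes, as above, and 3' over 5' for actin (1.6-fold, adjusted permutation p = 0.0497), while 3' over 5' for Gapdh did not pass (-0.57 on the log2 scale, adjusted p = 0.184). The shifts of these classes as a whole did not pass camera (adjusted p = 0.19 for UTR, 0.24 for unmarked and 0.19 for CDS). Here too the Fisher p-values do not measure the spread between arrays. The odds ratio for lower calls of UTR probe sets was 2.06 as reported, 1.68 with a pseudocount of 1 and 3.15 with 64. These shares were not matched on brightness. UNKN members were again called less often, 6.95% against 15% higher (adjusted p = 5.2e-13). Unmarked probe sets were called higher less often, at 11.9% against 14.7% (adjusted p = 0.0036), which was lost with a pseudocount of 64 (adjusted p = 0.075).

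Higher in hemocytes than in both other two-round tissues were 1356 probe sets, and lower than in both were 803. Heads had 607 and 262 such probe sets and carcasses 483 and 76. Independent lists of the same lengths would share 200.9, 78.9 and 64.4 higher and 128.3, 87.4 and 91 lower calls, while 20 simulations with unchanged groups made at most 1 call per contrast and so had 0 to share, which says nothing of lists this long. When the arrays of the tissue were split so that each contrast used 2 of its own, 1240, 584 and 416 probe sets were higher than both and 731, 314 and 73 lower. Ag.2R.1112.0_CDS_at led the hemocyte list. Few probe sets were seen in 1 tissue only, meaning above background on its 4 arrays and below it on all 8 of the other tissues, namely 41 for hemocytes, 34 for heads and 83 for carcasses. These small counts moved with the background, to 66 for heads and 146 for carcasses at the 99th percentile, and the head count rose to 57 without head replicate 2 and to 52 without head replicate 3.

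**Figure D2:**
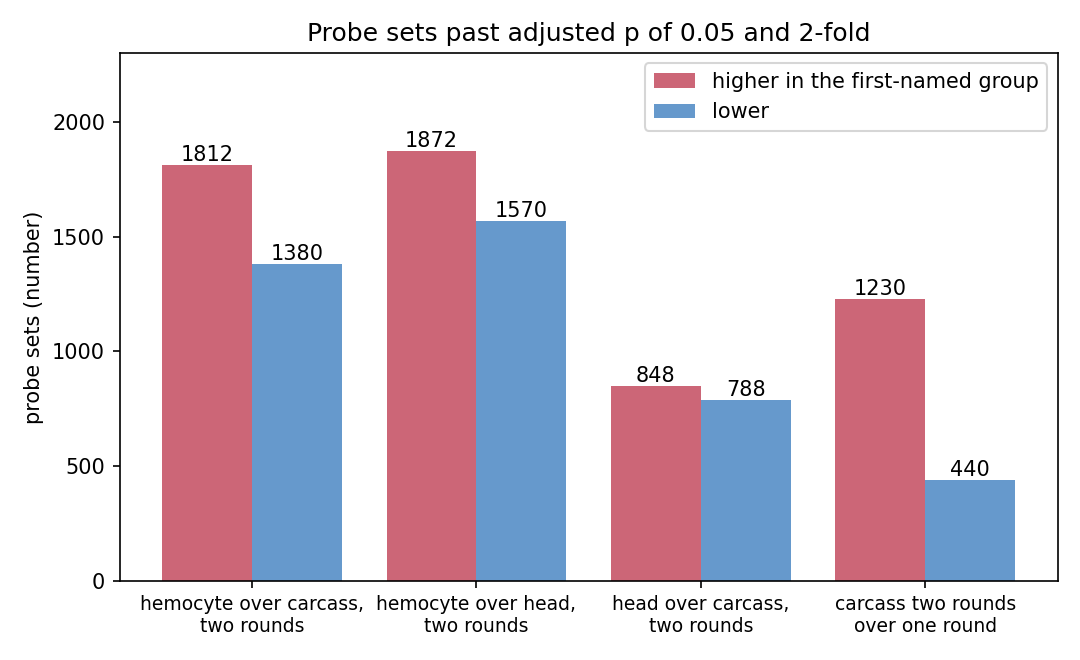
Bars give the number of Ag. probe sets called higher (red) or lower (blue) in the first-named group of each comparison, at a limma adjusted p under 0.05 and at least 2-fold. The hemocyte comparisons have the most calls, 3192 and 3442, against 1636 for head over carcass and 1670 for the 2 carcass labellings; the counts carry no error bars, and the carcass labelling split between higher and lower moves with the scaling.

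The comparison of heads with carcasses had about as many higher as lower calls. Ag.3R.2620.0_at measured 2017 ± 1360 in heads and 134.1 ± 198 in two-round carcasses (SD, n = 4; log2 difference 4.33 ± 0.85 SE, limma adjusted p = 0.0015), with 3 of 4 carcass arrays above background. The difference was 5.16 without carcass two-round replicate 3 (at 430, with 2 of the other 3 above background), 3.65 without carcass two-round replicate 1 and 4.92 without head replicate 2. Ag.2R.85.1_CDS_at measured 1135 ± 185 and 69.51 ± 29.1 (difference 3.81 ± 0.36, limma adjusted p = 8.5e-07). Ag.3L.163.0_CDS_at was at least 301-fold lower in heads, below background on all 4 head arrays, against 4215 ± 1360 in carcasses (limma adjusted p = 4.3e-13). Ag.3R.157.14_a_at measured 7.093 ± 6.72 in heads, with 1 of 4 arrays above background, and 6822 ± 2700 in carcasses (limma adjusted p = 4.3e-11), and against the other 3 head arrays, all below background, it was at least 489-fold lower. It was thus near or below background in heads and hemocytes and bright in both carcass groups, with 4372 ± 1900 after 1 round. The middle probe set of Gapdh was 2.88-fold lower in heads (exact permutation test, adjusted p = 0.0497), with the same direction under each of 3 other scalings, whereas its 3' probe set did not pass (0.02 on the log2 scale, -0.07 with median centring, adjusted p = 0.914). Its 3' over middle ratio was 2.91-fold higher in heads (adjusted p = 0.0497). The 5' probe set of actin was 1.37-fold higher in heads (adjusted p = 0.0497), and its middle probe set did not pass (0.07 on the log2 scale, -0.02 with median centring, adjusted p = 0.722).

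In all, 848 probe sets were called higher and 788 lower in heads, 1 of them at least 16-fold higher and 123 at least 16-fold lower. With median centring lower calls outnumbered higher ones, at 866 against 780. Unmarked probe sets were called higher most often, at 12.7% of 1809 against 5.47% of the others (odds ratio 2.5, Fisher's exact test, adjusted p = 3.6e-25), and CDS ones least, at 5.21% against 11.6% (adjusted p = 2.7e-27). UTR probe sets were at 9.03% against 6.31% (adjusted p = 0.0082), which was lost with a pseudocount of 1 (adjusted p = 0.12) and without carcass two-round replicate 1 (0.22), head replicate 1 (0.081) or head replicate 2 (0.076). The shift of the unmarked class as a whole, with a median of 0.192 against 0.068 for the others on the log2 scale, did not pass camera (adjusted p = 0.15, and 0.99 with an estimated correlation). Fisher's test counts probe sets of the same arrays as independent, so its p does not measure the spread between arrays. With one-round carcasses as the reference the calls numbered 3328, of which 1290 were shared in direction with the 1636 above. Independent lists would share 163.3, and with 2 head arrays in each list 1206 were shared against 165.1.

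**Figure D3:**
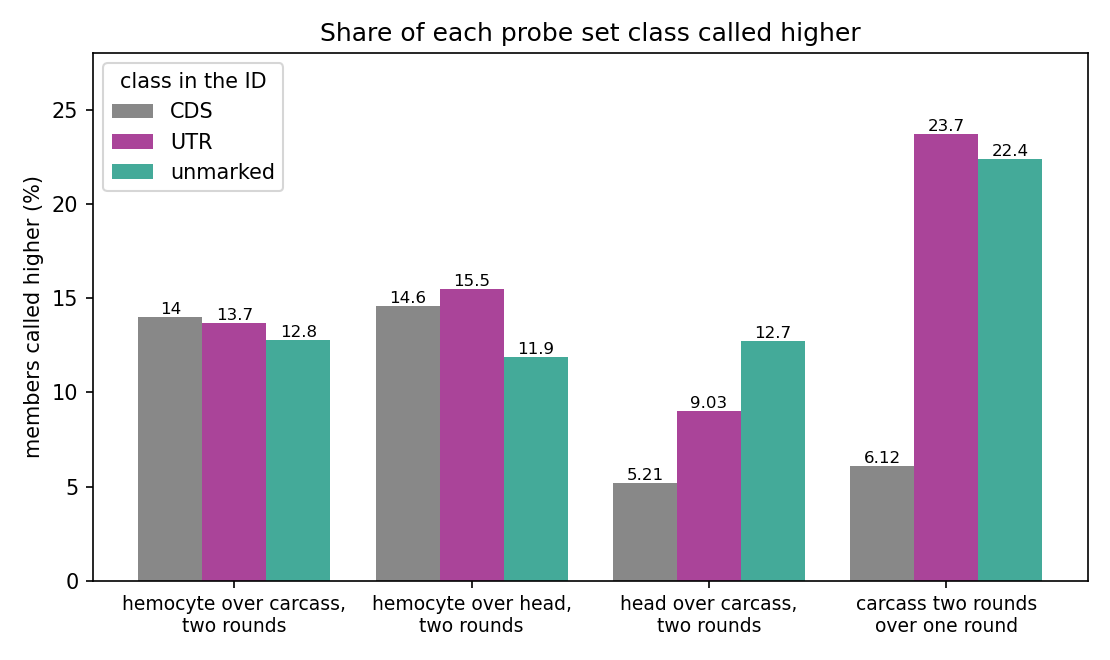
Bars give the percentage of bright probe sets of each class in the ID (10477 CDS, 775 UTR, 1809 unmarked) that were called higher in the first-named group of each comparison. After 2 rounds of amplification against 1 round, 23.7% of UTR and 22.4% of unmarked probe sets were called higher against 6.12% of CDS ones.

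The comparison of carcasses after 2 rounds and 1 round of amplification set 2 labellings of 1 tissue side by side, from 80 ng against 1000 ng of RNA. The control genes differed along their length. The 3' over 5' intensity ratio of Gapdh was 32.01 ± 6.23 after 2 rounds and 1.618 ± 0.223 after 1 round (SD, n = 4; 19.7-fold), and that of actin was 25.43 ± 3.3 and 2.634 ± 0.321 (9.65-fold), higher in 4 of 4 pairs of arrays for both. At the 5' ends Gapdh was 19.1-fold and actin 6.35-fold lower after 2 rounds, in 4 of 4 pairs and under each of 3 other scalings. At the 3' end actin was 1.52-fold higher, in 4 of 4 pairs and under each of 3 other scalings. Each of these 5 differences had an adjusted p of 0.0497 when all 8 arrays were permuted, but the carcass arrays are paired by number, and permuted within the 4 pairs none passed (exact p = 0.125, the smallest possible). Gapdh at its 3' end passed neither test (0.04 on the log2 scale, -0.15 with median centring and -0.07 with quantile normalization, adjusted permutation p = 0.879, and 0.625 within pairs). The other two-round tissues had high ratios too. Heads measured 72.91 ± 28.1 for Gapdh and 20.68 ± 3.55 for actin, and hemocytes 46.82 ± 10.7 and 12.83 ± 1.23. The actin ratio was lower in hemocytes than in both, as given above, while the Gapdh ratio did not differ past the threshold between two-round tissues (adjusted p = 0.122, 0.184 and 0.0879), although its 3' over middle ratio did between heads and the others.

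**Figure D4:**
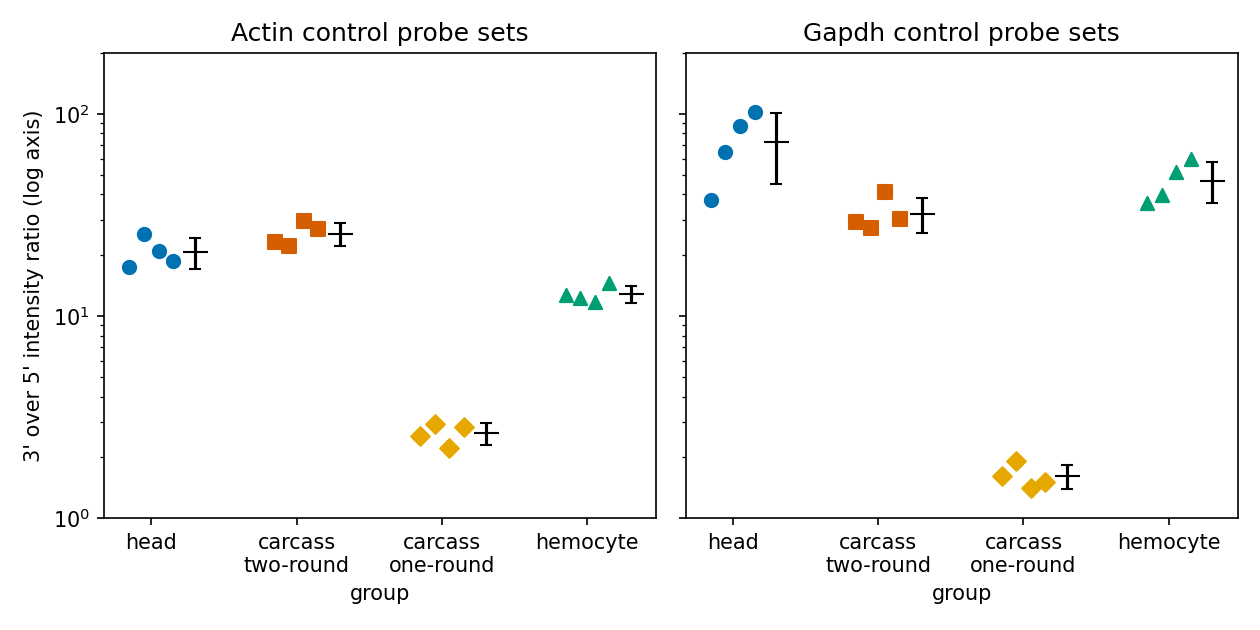
Each point is 1 array's 3' over 5' intensity ratio for the actin (left) and Gapdh (right) control probe sets on a log axis, by group, in the order of replicate number; the black mark and bar give the mean and SD of the 4 arrays. One-round carcasses lie at 2.634 and 1.618 on average, below every two-round array.

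The rate of higher calls differed between the classes of probe sets. UTR probe sets were called higher after 2 rounds in 23.7% of cases against 8.51% of the others (Fisher's exact test, adjusted p = 2.2e-33) and unmarked ones in 22.4% against 7.33% (adjusted p = 1.6e-72), while CDS ones were in 6.12% against 22.8% (adjusted p = 3e-121). The rate of lower calls passed for no class, at 2.19% for UTR (adjusted p = 0.11), 3.26% for unmarked (0.91) and 3.47% for CDS probe sets (0.27). Median log2 differences were 0.554 for UTR, 0.409 for unmarked and 0.146 for CDS probe sets (0.24, 0.23 and 0 with quantile normalization), and with the preset correlation camera gave adjusted p of 1.3e-05, 0.00017 and 1.3e-05. None of the 3 passed with an estimated correlation (adjusted p = 0.87 with an estimated correlation for each). The Fisher p-values, which count probe sets of the same arrays as independent, do not measure the spread between arrays. Probe sets on the X were called higher in 6.2% of cases against 9.71% (adjusted p = 0.00069) and lower in 4.81% against 3.24% (adjusted p = 0.039), of which the former was lost under quantile normalization (adjusted p = 0.2) and with a pseudocount of 64 (0.18). The latter was lost without carcass two-round replicate 1 (0.087), 3 (0.096) or 4 (0.075), carcass one-round replicate 3 (0.061) or 4 (0.17), or head replicate 4 (0.056), and under 3 other settings (0.06 to 0.42). UNKN probe sets as a whole were called higher less often, at 7.14% against 9.62% of the others (Fisher's exact test, adjusted p = 0.039). This was lost under quantile normalization (adjusted p = 0.76), among other settings. A set of 11 probe sets, all with UNKN in their ID, rose by at least 154-fold each, taken against the higher of background and measured value, while no other called probe set had a fitted rise over 3.01 on the log2 scale. On the one-round arrays 1 of the 11 was below background on all 4, 9 were above it on some and 1 on all 4. Ag.UNKN.2231.0_s_at measured 7070 ± 1410 after 2 rounds against a level below background on all 4 one-round arrays (at least 725-fold, limma adjusted p = 1.5e-12). Ag.UNKN.2433.0_s_at measured 7631 ± 913 against 6.425 ± 4.57 (limma adjusted p = 8.4e-14), with 1 of 4 one-round arrays above background, and was at least 770-fold higher than on the other 3. The 11 were bright in heads and hemocytes as well, with means from 1380 to 10600. Lower after 2 rounds were Ag.X.80.0_CDS_a_at, at 157.2 ± 81.5 against 2351 ± 1690 (-3.66 ± 0.65, limma adjusted p = 0.00072), and Ag.2R.329.3_s_at, at 13.69 ± 6.1, with 2 of 4 two-round arrays above background, against 334 ± 35.9 (-3.58 ± 0.17, limma adjusted p = 1.2e-09).

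After 2 rounds 1230 probe sets were called higher and 440 lower than after 1 round. The balance depended on scaling: 73.7% of the calls were higher as deposited, 86.6% with hybridisation spike-in scaling, 61.6% with median centring and 40.5% with quantile normalization, and the median log2 difference of all probe sets was 0.12, 0.21, 0 and 0.02. One-round replicate 3 was brighter than its group, with a trimmed mean of 122.2 against 82.83 to 86.4, and without it 1610 were called higher and 342 lower.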

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

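The level test of spike-in carry-over, the tests of scaling and of 3' shortening, and the shares of carcass or head RNA in this part were chosen only after the result was seen, while the correlation test of carry-over, the splits of the arrays, the shared sequence, the brightness and the tissue RNA tests were set beforehand, the last after single values of hemocyte replicate 4 had been seen.

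In 10 of 112 groups of 4 arrays 1 array stood far from its group, where chance gives about 1 in 20, or 5.6. Ag.2L.245.0_CDS_at measured 117 in head replicate 1 and 7750 to 10100 in the other heads. Ag.UNKN.2231.0_s_at measured 2790 in head replicate 1 and 5330 to 6030 in the others. In hemocyte replicate 4, Ag.3R.3.3_UTR_a_at measured 1590 against 1.01 to 1.59, and Ag.3R.3.1_CDS_a_at 391 against 1.57 to 3.84. Ag.3L.163.0_CDS_at measured 7.51 in hemocyte replicate 1 against 1.14 to 1.96, all below background. Ag.X.80.0_CDS_a_at measured 27.4 in hemocyte replicate 2 against 5.05 to 6.49. Ag.3R.2620.0_at measured 291 in carcass one-round replicate 3 against 23.8 to 38.8, and 430 in the two-round carcass array of that number. The 3' actin control had a log2 intensity of 13 in hemocyte replicate 1 against 13.3 in the others, and the 5' actin control 11.3 in carcass one-round replicate 3 against 10.5. Carcass one-round replicate 3 also had a trimmed mean intensity of 122 against 82.8 to 86.4. Among probe sets left out of the comparisons, 21 of 937 named by accession had a group mean over 100. So did 3 of 4506 whose ID begins with Pf, with or without a dot after it. The 12 poly-A spike-in probe sets, for transcripts added before labelling, were 7.53-fold higher after 2 rounds than after 1 round, in 4 of 4 pairs of arrays (exact permutation test within pairs, p = 0.125, the smallest it can give).

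Splits of the arrays argued against chance as the source of the tissue calls. They cannot tell tissue from collection or, for hemocytes, from extraction method, and 1 of 35 is the smallest share possible. A split that mixes distinct groups widens the spread, so few calls were likely in it beforehand. Of the 35 splits of 8 arrays, only 1, the real one, gave as many calls for hemocytes and carcasses (3195 in a fit of the 2 groups, highest other 0), for hemocytes and heads (3399, highest other 0) and for heads and carcasses (1587, highest other 4). For the carcass labellings, splits that part all 4 pairs of numbers are 8 in all, too few for a share under 0.05. The real one gave 1648 calls and the highest other 0, and the gap between UTR and CDS medians was 0.41 against at most 0.25. Splits argued against chance for the enriched probe sets as well, and again cannot tell tissue from collection or, for hemocytes, from extraction method. Among 100 splits of the 12 two-round arrays, 1 gave as many hemocyte-enriched probe sets as the real split (1349, highest other 0) and 1 as many head-enriched ones (601, highest other 414, with the 4 two-round carcass arrays in the place of heads). For carcasses 2 of 100 did (490, highest other 1467). That other split had the 4 hemocyte arrays in the place of carcasses, so it follows the tissues, and the next highest count was 419.

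The 11 UNKN probe sets bright after 2 rounds had means of 2470 to 9100 in two-round and 2.91 to 31.4 in one-round carcasses. Each of the 11 had a fitted rise at least 3.63 (log2) beyond the rise of 2.91 of the poly-A spike-ins. Taken against the higher of background and measured value, the rise was at least 4.36 beyond it. The 11 were picked for a fitted rise of at least 16-fold, so this level test could hardly fail and cannot decide on carry-over. A first test of it, their correlation over 12 two-round arrays within tissues (Pearson r = 0.03, permutation p = 0.92; Spearman rho = 0.15, permutation p = 0.65; r = 0.18 without the 2 farthest arrays), decided nothing, as its interval ran from -0.61 to 0.65. A scaling common to all probe sets was excluded, since their median rise was 0.116 against a fitted 7.35 for the 11. A sequence shared by the 11 and made in the second round is a candidate explanation, since their deviations within tissues went together (median r = 0.8 over 55 pairs, lowest 0.52), though an array-wide yield of the second round would give the same, and no biological explanation was tested because both labellings are of carcasses.

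UTR probe sets lay above CDS probe sets after 2 rounds by 0.41 (log2), with medians of 0.24 and 0 under quantile normalization. Shortening of the labelled RNA towards the 3' end is consistent with the control genes, whose 3' over 5' ratios were higher after 2 rounds by at least 3.27 on average and by at least 2.93 in each of 4 pairs. A difference in brightness between the classes stays open, since the gap matched on brightness was 0.21, between 0.35 and 0.7 of the unmatched one in the 4 pairs of numbers. In heads against two-round carcasses, where unmarked probe sets lay above CDS ones by 0.13, brightness did not account for this gap of medians (matched gap 0.2). The share of unmarked probe sets called higher was not matched on brightness, so for that share brightness stays open. Stronger shortening in heads cannot be told apart from a tissue difference, because the actin ratios differed by -0.3 (3' over 5') and 0.08 (3' over middle), neither past the threshold, and the Gapdh ratios by 1.11 and 1.54, of which the second passed (exact permutation test, adjusted p = 0.0497, from 0.029, the smallest possible).

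Hemocyte replicate 4 lay far above the other hemocyte arrays at the 2 arm 3R probe sets given above, for which it would need a share of 21.2% and 13.6% of carcass RNA or of 10.2% and 3.58% of head RNA. RNA of whole carcasses at such shares was excluded as the source, since 264 probe sets low in the other hemocyte arrays gave a median share of 0.06% (quartiles -0.2% and 1.1%), and 35.2% of them were highest in replicate 4 (exact 95% interval 29.5 to 41.3), where such RNA would raise nearly all. RNA of whole heads at such shares was excluded likewise, with a median of 0.71% (quartiles -0.1% and 1.9%) and 46.1% of 180 highest (38.7 to 53.7), as was a brighter array, with a median difference of 0.06. For each other hemocyte array, with probe sets chosen as low in the 3 remaining ones, at most 27.8% and 30% were highest in it, and what sets replicate 4 apart stays open. Ag.2L.245.0_CDS_at, at 5671 in carcasses, was at 1.42 in replicate 4.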

How the results depend on the processing

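The spike-in scaling, the one-round carcass reference, the 99th percentile background, the block within carcass arrays and all alternatives for class shifts, detection and control ratios were chosen after seeing the data, while shares were run under the settings planned for the calls and under spike-in scaling. No named probe set, control ratio or share of an arm or class changed direction under the alternatives run for it. The balance of calls turned from more higher to more lower under quantile normalization for hemocyte over carcass (1325 higher, 1399 lower) and for 2 rounds over 1 round, and under median centring (780 and 866) and a pseudocount of 64 for head over carcass. All calls of named probe sets held under the alternatives run for them, and counts stayed within 1.5 times in 187 of the cases with all arrays and moved further in 25. A pseudocount of 64 gave 1970 calls for hemocyte over carcass (1087 higher, 883 lower), 2188 for hemocyte over head (928 lower), 962 for head over carcass (466 higher, 496 lower), 790 for 2 rounds over 1 round (606 higher, 184 lower) and 352 head-enriched probe sets. A pseudocount of 1 gave 2605 for 2 rounds over 1 round (1911 higher, 694 lower). Quantile normalization gave 577 higher and 848 lower in that comparison, and spike-in scaling 1854 and 288. With one-round carcasses as reference 3169 were higher in hemocytes, and heads gave 3328 calls (2252 higher) and 6021 at any fold. Class shifts of 0.15 (CDS), 0.55 (UTR) and 0.41 (unmarked) lost their call with an estimated correlation (adjusted p = 0.87; from 6.1e-07 for UTR over its alternatives). The 99th percentile background gave 66 head-only and 146 carcass-only probe sets. The causes were not tested. Signal over background limits the folds given as bounds, and 1563 probe sets were above background on none of the 16 arrays.

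Without 1 array at a time the calls ranged from 3025 to 3313, 3337 to 3608, 1559 to 1699 and 1510 to 1952 in the 4 comparisons, and the enriched counts from 1216 to 1455, 578 to 645 and 447 to 496. Head-only probe sets ranged from 34 to 57, the highest without head replicate 2. Shares of arms and classes among calls kept their side of the threshold in 336 cases with 1 array left out and 204 with other alternatives, and lost it in 16 of each kind.

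The replicate number as a block gave 3203, 3445, 1652 and 1685 calls, and 1747 within the carcass arrays, where the numbers pair the arrays. It changed no call of a named probe set and moved no count by over 1.5 times. Permuted within the pairs of carcass arrays, a test chosen after seeing the data, the 3' over 5' ratios of actin (3.27) and Gapdh (4.3) lost their call at an exact p of 0.125, since 4 pairs can give no smaller one.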

Other observations

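The test of ID neighbours, the split for probe sets low in a tissue and the counts of Pf. probe sets by direction at an unadjusted p were chosen only after the result was seen, and the test of the Pf. probe sets beforehand. In hemocytes 803 probe sets were lower than in both heads and carcasses. With their arrays split so that each contrast used 2, 731 were lower than both, against 123.2 for independent lists of those lengths. Heads had 314 in such a split against 84.1, and carcasses 73 against 84.1. Among the probe sets low in hemocytes was Ag.2L.245.0_CDS_at, at 3.034 ± 2.37 (SD, n = 4), against 5671 ± 352 in two-round carcasses, 5589 ± 805 in one-round carcasses and 6879 ± 4620 in heads.

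The collection note calls the hemocyte donors infected, while the design calls the females naive. If the hemocyte pools had held more malaria parasite RNA than heads and carcasses, Pf. probe sets would be higher in hemocytes. Of 4502 tested with limma, 1 was called higher in hemocytes than in both other tissues, as was 1 in heads and 0 in carcasses, and 336 had an unadjusted p under 0.05 for hemocytes over carcasses, where chance gives 225.1, with 109 of them higher and 227 lower in hemocytes. For hemocytes over heads 313 did, 135 higher and 178 lower, and for heads over carcasses 331. This argues only against an excess of parasite RNA in the hemocyte pools large enough to lift these probe sets well past the pseudocount of 16. It also rests on the reading of the Pf. prefix used here. The median intensity of the Pf. probe sets lay between 1.367 and 2.691 on all arrays, so a smaller excess could hardly be called. Parasite RNA at like levels in all tissues would not show in this test, so it does not settle whether the females were infected. The probe sets named next were chosen after their values were seen. The one higher in hemocytes, Pf.UN_2.5.0_CDS_at, measured 30.9 ± 8.18 there (SD, n = 4), 2.89 ± 1.28 in heads and 6.59 ± 3.02 in two-round carcasses. The one higher in heads, Pf.6.239.0_CDS_s_at, measured 635 ± 533 there, 122 ± 26.7 in two-round carcasses and 95.2 ± 12.6 in hemocytes. It is among the 3 with a group mean over 100, with Pf.12.514.0_CDS_at (294 ± 235 in hemocytes, 292 ± 233 in heads) and Pf.1.76.0_CDS_at (121 ± 117 in hemocytes, 97.8 ± 145 in heads).

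Changes were compared between probe sets with neighbouring numbers in their IDs. For hemocytes over carcasses the correlation over 7136 pairs was 0.048, against at most 0.039 in 1000 shuffles. It was 0.045 for hemocytes over heads, 0.097 for heads over carcasses and 0.033 for 2 rounds over 1 round, for which no shuffles were run. A hypothesis that neighbouring IDs share a tissue bias was left undecided by this small value, and probe sets are not independent replicates.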
